A study of Mus musculus with 4 samples.

How the data were processed

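CD4+ thymocytes were sorted from pooled thymi of 8-week-old C57BL/6N mice that were wild type (WT) or lacked the microRNA gene Mir142 (miR-142-/-), and RNA from each sorted population was hybridised to 1 Affymetrix Mouse Gene 1.0 ST array. Per the labels, the WT pool held 5 mice (3 females and 2 males) and the miR-142-/- pool 4 mice (1 female and 3 males). Each pool gave a less mature CD69+ Qa2- population and a more mature CD69- Qa2+ population, so there were 4 arrays and 1 array per group. The free-text description of the miR-142-/- Qa2- sample names Qa2+ cells, while its title and its sorting entry name Qa2- cells. The title and the sorting entry were used.

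The deposited values are log2 expression values per probe set. RMA and Partek are named in the submitters' processing notes, with versions not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays and summarises probes on the log2 scale, which compresses differences of dim probe sets and hides a shift shared by all genes. Every other step was computed from the deposited table.

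The table held 35557 probe sets, of which 21789 had 1 listed gene, 1621 had several and 12147 had none in the platform annotation used here. Probe sets with several genes named no gene, which leaves out most H2-Q genes. Of the 21789, 21698 matched a current mouse gene record (GRCm38.p6) by Entrez ID. Each of 19938 genes took the probe set with the highest mean over the 4 arrays, a choice that concerned the 999 genes with several probe sets. Genes counted as above background when that mean exceeded log2 5.87, the 95th percentile of 1194 olfactory and vomeronasal receptor genes, which left 12591 genes. Short probes can cross-hybridise between close paralogs, so values of H2-Q, Klra, Ms4a, Ifit and histone genes are less certain than others.

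Genotype differences were miR-142-/- minus WT within a sorted population, and stage differences were Qa2+ minus Qa2- within a genotype. With 1 array per group these have no replicate check and no p-value, and genes at least 2-fold apart were counted. Where the dimmer value lay below background, a fold is given as a lower bound against the threshold, a choice made after seeing the data, and log2 differences of such genes may be compressed. The standard deviation of the differences of receptor genes was 0.15 and 0.18 for genotype in Qa2- and Qa2+ cells. It was 0.22 and 0.21 for stage in WT and miR-142-/-. This describes scatter at low signal and not the spread between mice. For stage it holds more than independent array noise, since the stage differences of receptor genes correlated at 0.47 between the genotypes. Genes at least 1.5-fold apart in the same direction in both populations were set beside the number expected from independent lists. The stage difference averaged over genotypes was tested with limma (version 3.58.1, R 4.3.3), with genotype as a block, 2 pairs, 1 residual degree of freedom, a prior of 6.94 degrees of freedom and Benjamini-Hochberg adjustment (two-sided, threshold 0.05). The pairs are pools rather than mice. Because the prior outweighs the 1 residual degree of freedom, SEs and p-values rest mostly on the spread between these pairs pooled over all genes. They rest little on the spread of the single gene, and do not measure that between mice.

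Gene lists were fixed before the data were examined: immature and mature single-positive thymocytes, egress and homing, T cell receptor immediate-early genes, NF-kB, interferon response, DNA replication, G2 and mitosis, cell cycle regulators, reported miR-142 targets, genes near Mir142, microRNA machinery, actin cytoskeleton, apoptosis, cytokine receptors, T cell transcription factors, CD4 T cell identity, heat shock and stress, glycolysis and sex-linked genes. Marker lists of other cells covered double-positive, CD8 single-positive, regulatory, innate-like, gamma-delta and effector or recirculating T cells, B cells, myeloid and dendritic cells, erythroid cells and thymic stroma. The median difference of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Members at least 1.5-fold apart were counted.

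Named genes followed a rule set before the data were examined. It took the genes that check the labels, the 10 genes with the largest difference in each direction shared by both populations or both genotypes, ranked by the smaller of the 2 differences, and the 5 largest in each direction in each single comparison and in the difference of differences. It added up to 4 members of each list with the largest differences and members counted as 1.5-fold apart. In the lists of miR-142 targets and of genes near Mir142, some members with small differences were named outside this rule. Predicted genes, receptor genes and antigen receptor segments were left out.

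In simulated data for the averaged stage comparison, 12591 genes were fitted and 200 were changed. The fit called 98.0% of 2-fold and 100.0% of 4-fold changes. Of its 220 calls, 10.0% were unchanged genes, a share above the adjusted p threshold of 0.05. The noise of each gene was drawn from the prior that the same fit had estimated, so these rates come from data that meet its assumptions. Far fewer genes were changed than the 1651 called in the real data. Simulated noise was independent between arrays, and the simulated stage effect was equal in both genotypes. Differences that both real pairs share without a change in expression are therefore not covered. Of unchanged lists of 20 genes, 2.0% lay outside the central 95% of random lists. Alternatives were centring, quantile normalization, other background filters, the mean of all probe sets of a gene, other thresholds, other fits and other list settings. Counts without X and Y genes and without the genes of the DNA replication and the G2 and mitosis lists were added after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Sites for miR-142 in 3' untranslated regions were not analysed here.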

Results

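Expression was measured on 4 arrays, 1 for each of WT Qa2-, WT Qa2+, miR-142-/- Qa2- and miR-142-/- Qa2+ CD4+ thymocytes. Qa2 and CD69 separate newly selected CD4 single-positive thymocytes (CD69+ Qa2-) from mature cells close to leaving the thymus (CD69- Qa2+), and miR-142 is a microRNA abundant in blood cells. The design asks how loss of miR-142 alters gene expression at each stage and how the stages differ. Array medians over all 35557 probe sets were log2 6.71 and 6.61 for WT Qa2- and Qa2+ cells and 6.74 and 6.67 for miR-142-/- Qa2- and Qa2+ cells. The correlation across probe sets between arrays was 0.982 to 0.991, and the number of arrays limits the precision.

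The Mir142 probe set read log2 10.11 and 9.41 in WT Qa2- and Qa2+ cells and 5.29 and 4.88 in the miR-142-/- cells, below the background threshold of 5.87. Cd69, an activation marker lost during maturation, was 1.71-fold lower in Qa2+ than in Qa2- cells of WT and 1.95-fold lower in miR-142-/-. The class Ib genes H2-Q4 and H2-Q5, relatives of the genes that encode Qa2, were higher in Qa2+ cells by 0.63 and 0.84 in WT and by 0.73 and 0.96 in miR-142-/-. H2-Q2 differed between stages by -0.01 and -0.12, and H2-Q10 was below background. Cd4 lay between 12.36 and 12.64 on all arrays and Cd8a between 7.25 and 7.53, while Cd8b1 differed between miR-142-/- and WT by -0.73 in Qa2- and -1.23 in Qa2+ cells.

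Sex-linked genes did not match the labelled pools of both sexes. Xist, the RNA of the inactive X chromosome, read 12.67 and 12.14 in WT and 5.06 and 4.83 in miR-142-/- cells. The Y-linked genes Eif2s3y, Kdm5d and Uty lay between 4.29 and 5.09 in WT, below the background threshold, and between 9.72 and 10.58 in miR-142-/-. Every genotype difference below therefore also compares arrays that differ in these sex-linked transcripts.

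**Figure D1:**
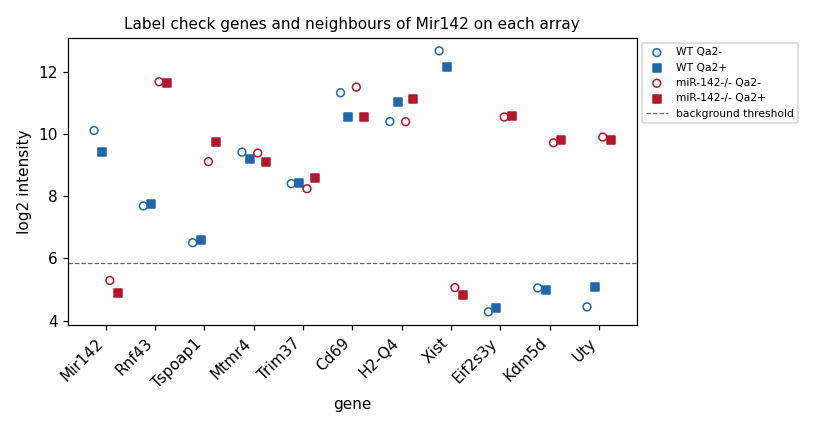
Log2 intensity of genes that check the labels and of genes near Mir142, 1 point per array, with WT in blue, miR-142-/- in red, Qa2- as open circles and Qa2+ as filled squares, and a dashed line at the background threshold of 5.87. Mir142 and Xist lie below the line only in miR-142-/-, the Y-linked genes only in WT, and Rnf43 is near 7.69 in WT Qa2- and 11.68 in miR-142-/- Qa2- cells.

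Ranked by the smaller of the differences in Qa2- and Qa2+ cells, the gene with the largest increase in miR-142-/- outside the Y chromosome was Eya1, a transcriptional co-activator and phosphatase of organ development. It was below background on the WT arrays (4.87 and 4.83), and at least 21.5-fold higher in Qa2- and at least 16.1-fold higher in Qa2+ cells when measured against the threshold. Rnf43, a ubiquitin ligase that restrains Wnt receptors, was 15.9-fold and 14.7-fold higher. The transcription factor Klf12 was 8.27-fold and 9.12-fold higher, followed by the membrane proteins Tmem176a (8.21-fold and 8.14-fold) and Tmem176b (7.46-fold and 8.90-fold), the semaphorin receptor Nrp2 (8.51-fold and 6.84-fold) and the steroid-metabolising enzyme Akr1c18 (6.30-fold and 7.54-fold). Eif2s3y, Uty and Kdm5d completed the 10 genes with the largest shared increase by this ranking.

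Apart from Xist and Mir142, the largest shared decrease by the same ranking was in Ctla4, an inhibitory receptor of T cells, 6.11-fold lower in Qa2- and 6.28-fold lower in Qa2+ cells. The mitotic checkpoint kinase Bub1 was at least 4.07-fold lower in Qa2- cells, where it was below background in miR-142-/-, and 6.62-fold lower in Qa2+ cells, and the proliferation marker Mki67 was 5.26-fold and 5.30-fold lower. Ccna2, a cyclin of S and G2 phase, was 4.93-fold and 6.79-fold lower, the spindle protein gene Nusap1 4.85-fold and 8.21-fold, the ribonucleotide reductase subunit gene Rrm2 4.50-fold and 4.77-fold, and the mitotic motor gene Kif15, below background in miR-142-/-, at least 3.69-fold and 4.16-fold. Neurl3, a ubiquitin ligase gene below background in miR-142-/- Qa2- cells, was at least 3.30-fold lower there and 5.70-fold lower in Qa2+ cells.

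At least 1.5-fold differences shared by both populations were found for 270 genes higher and 347 lower in miR-142-/-, against 17.8 and 23.0 expected from independent lists, and 2 genes differed in opposite directions. At 2-fold the counts were 89 and 124. The correlation of the genotype differences across genes was 0.78 (Spearman 0.62), and 0.10 for receptor genes. Genes are not independent replicates, and both populations came from the same pools, so agreement between them does not measure the spread between mice.

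**Figure D2:**
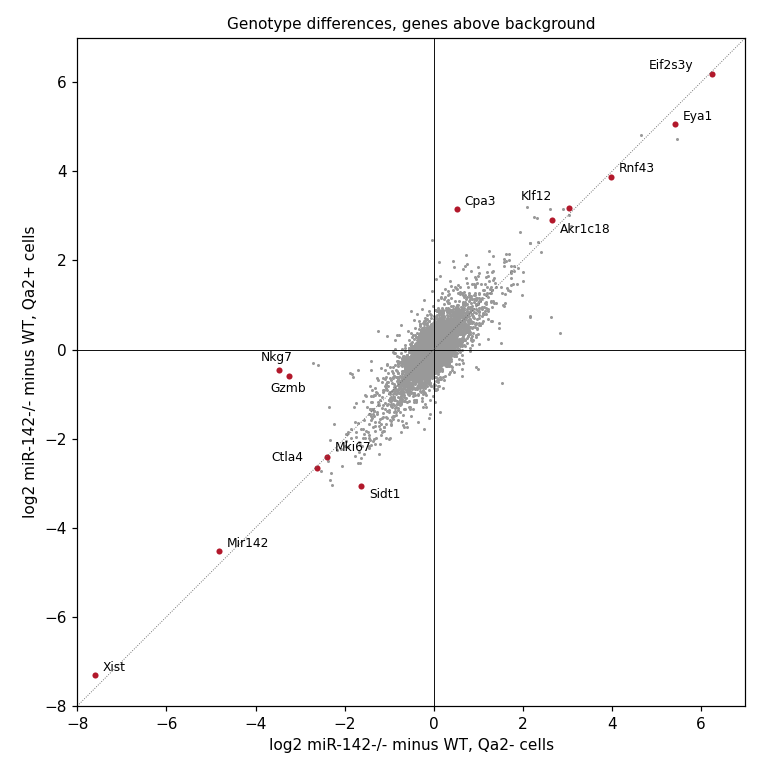
Log2 difference between miR-142-/- and WT in Qa2- cells (horizontal) and Qa2+ cells (vertical) for 12591 genes above background, 1 point per gene, with named genes in red and a dotted line of equality. Eya1 and Rnf43 lie far up the line, Xist, Mir142 and Ctla4 far down it, and Nkg7, Gzmb and Cpa3 away from it.

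The proliferation lists were lower as groups. Of 33 DNA replication genes above background, 28 were at least 1.5-fold lower in miR-142-/- Qa2- cells and 27 in Qa2+ cells, with medians of -1.08 and -0.95, below all 10000 random lists. Pole, a replicative polymerase gene, differed by -2.33 and -2.03, and Dtl, Ccne2 and Prim1 differed by -1.86, -1.36 and -1.81 in Qa2- and by -1.98, -2.06 and -0.63 in Qa2+ cells. Of 36 G2 and mitosis genes, 34 and 35 were at least 1.5-fold lower, with medians of -1.21 and -1.74, again below all random lists. Top2a, the topoisomerase of dividing cells, differed by -2.05 and -2.62, and Kif11 by -1.78 and -2.38. Among 23 cell cycle regulators, with medians of -0.17 and -0.10, the E2F family repressor E2f8 differed by -1.57 and -2.35 and the CDK inhibitor Cdkn2c by -1.46 and -1.98. Leaving out the genes of both proliferation lists, a choice made after seeing the data, left 270 genes higher and 286 lower in both populations.

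Interferon response genes were also lower in miR-142-/-. Of 35 genes, 9 in Qa2- and 12 in Qa2+ cells were at least 1.5-fold lower, with medians of -0.34 and -0.44, below all random lists. The antiviral genes Rsad2 (-1.17 and -1.91), Oas2 (-1.16 and -1.54), Ifit3 (-1.44 and -1.45) and Ifit1 (-0.87 and -1.31) were among them, while Gbp3 differed by 0.67 and 0.43.

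Markers of innate-like and effector T cells were lower in miR-142-/- as well. The median of 15 innate-like genes was -1.04 in Qa2- and -0.59 in Qa2+ cells, and that of 17 effector or recirculating genes was -0.64 and -0.60, all below every random list. Cxcr6, a chemokine receptor of tissue-resident T cells, differed by -2.36 and -1.30, the interleukin receptor chain Il2rb by -1.04 and -1.37, Lgals1, a galectin, by -1.46 and -2.16, and Crip1 by -2.23 and -1.66. CD8 single-positive markers had medians of -0.76 and -0.28, and Ccl5 among them differed by -1.59 and -1.17. Regulatory T cell genes had medians of -0.03 and -0.51 at percentiles 43.84 and 0.0. Foxp3, their defining transcription factor, differed by -1.19 and -1.66, while Gpr83 differed by 1.03 and 1.27.

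The mature and immature single-positive lists differed in opposite directions. The 17 mature single-positive genes had medians of -0.42 and -0.35, with S1pr1, the receptor for egress from the thymus, at -1.70 and -0.46 and Ms4a4c at -1.33 and -1.63. The 20 immature single-positive genes had medians of 0.18 and 0.32, with the homing receptor Ccr9 at 0.05 and 1.58 and Ccr8 at 0.81 and 1.14. The egress and homing list had medians of -0.10 and -0.15, at percentiles 5.56 and 2.1, with Cxcr4 at 1.23 and 1.17 and the integrin Itgae at -1.41 and -1.58.

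The 19 reported miR-142 targets above background had medians of 0.25 and 0.34, above all 10000 random lists, but means of 0.09 and 0.07, at percentiles 93.83 and 81.74. Adcy9, an adenylyl cyclase, was 0.73 and 0.48 higher, and Cfl2, an actin-severing cofilin, 0.50 and 0.78 higher. The glucocorticoid receptor gene Nr3c1 differed by 0.46 and 0.58 and the cell cycle inhibitor Cdkn1b by 0.32 and 0.27. E2f7 and E2f8, which are also cell cycle genes, differed by -0.92 and -1.57 in Qa2- and by -0.99 and -2.35 in Qa2+ cells. Of the 19 genes, 13 were above 0 and 6 below in Qa2- cells, and 12 and 7 in Qa2+ cells, so genes besides these 2 were lower. At least 1.5-fold, 2 and 3 genes were higher and 2 and 2 lower, not all of them named here.

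Near Mir142, Tspoap1 was 2.61 and 3.16 higher and Rnf43 3.99 and 3.87 higher in miR-142-/-, whereas Mtmr4 (-0.03 and -0.09), Septin4 (0.26 and -0.10) and Trim37 (-0.16 and 0.14) differed by less than 1.5-fold. Mpo differed by 0.29 and 0.62. The list of 6 such genes had medians of 0.27 and 0.38.

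Medians in Qa2- and Qa2+ cells were 0.03 and 0.07 for microRNA machinery, -0.02 and -0.08 for the actin cytoskeleton, 0.07 and -0.06 for NF-kB, 0.02 and -0.07 for apoptosis and 0.16 and 0.00 for cytokine receptors. They were 0.07 and 0.02 for T cell transcription factors, 0.10 and 0.13 for CD4 T cell identity, 0.03 and 0.13 for heat shock and stress and -0.08 and -0.18 for glycolysis. Members apart from their list were the NF-kB adaptor gene Traf1 (-1.74 and -1.96), the pro-apoptotic genes Bmf (0.84 and 1.76) and Bbc3 (0.67 and 1.04), the stress gene Ddit4 (1.79 and 1.76) and the transcription factor gene Myb (0.63 and 1.28). T cell receptor immediate-early genes had a median of 0.00 in Qa2- and -0.32 in Qa2+ cells, the latter at percentile 0.0 with 6 of 24 genes at least 1.5-fold lower, and there Nr4a3, Fosl2 and Dusp5 differed by -0.92, -0.89 and -0.79. Markers of other cells had medians of 0.00 and 0.30 (double-positive thymocytes), 0.09 and 0.16 (gamma-delta T cells), -0.01 and -0.01 (B cells), 0.11 and -0.33 (myeloid and dendritic cells), 0.12 and -0.20 (erythroid cells, 3 genes) and 0.11 and 0.07 (thymic stroma). The following lists of this paragraph lay outside the central 95% of random lists. In Qa2- cells they were cytokine receptors (percentile 99.97), T cell transcription factors (98.26) and CD4 T cell identity (98.1). In Qa2+ cells they were immediate-early genes, double-positive thymocytes (99.96), myeloid and dendritic cells (0.0) and glycolysis (1.6). For cytokine receptors in Qa2- cells the list mean was -0.01, so the mean showed no such difference.

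**Figure D3:**
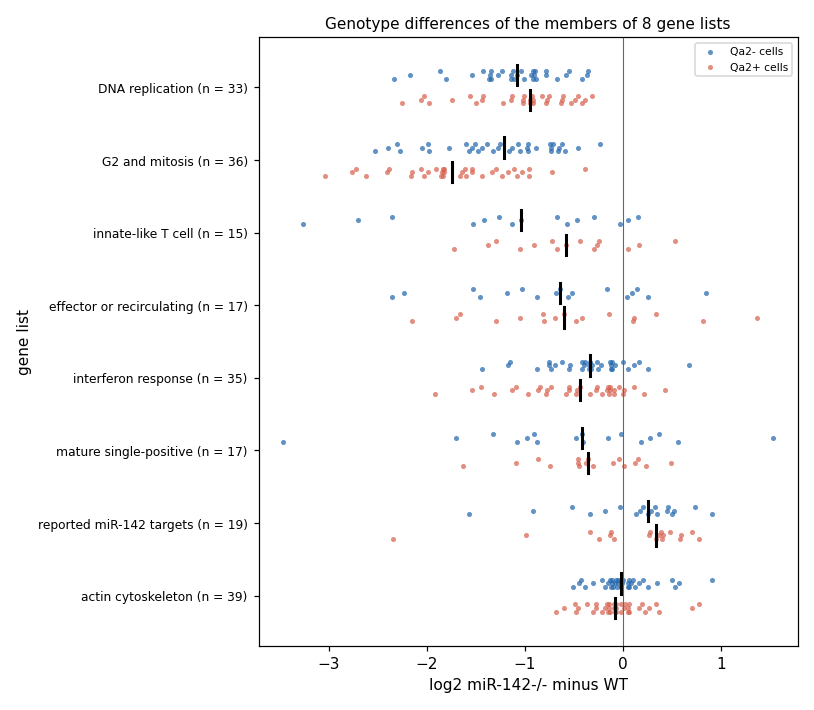
Log2 difference between miR-142-/- and WT (horizontal) for the members of 8 gene lists (vertical), 1 point per gene above background, with Qa2- cells in blue, Qa2+ cells in red and black bars at the medians. All members of both proliferation lists lie below 0, with medians of -1.08 and -0.95 for DNA replication and -1.21 and -1.74 for G2 and mitosis.

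In the comparison of Qa2- cells, 131 genes were at least 2-fold higher and 163 lower in miR-142-/-. Of these, 89 and 124 were also at least 2-fold higher and lower in Qa2+ cells. Besides genes already named, the largest decreases included Nkg7, a granule membrane protein gene, 11.1-fold lower, the protease gene Gzmb and the natural killer receptor gene Klrd1. Gzmb and Klrd1 were below background in miR-142-/- Qa2- cells (5.62 and 5.26), at least 8.09-fold and 4.27-fold lower than in WT. In Qa2+ cells Nkg7 differed by -0.45 on the log2 scale, while Gzmb and Klrd1 read 6.02 and 6.13 in WT and were below background in miR-142-/-, so the size of their difference there is not measured.

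In the comparison of Qa2+ cells, 180 genes were at least 2-fold higher and 234 lower, including the 89 and 124 shared with Qa2- cells. The largest decreases there included Sidt1, a transmembrane RNA transporter family gene, 8.32-fold lower in Qa2+ and 3.09-fold lower in Qa2- cells, and Nusap1 and Ccna2. Without X and Y genes, a choice made after seeing the data, the counts were 126 and 157 in Qa2- and 171 and 228 in Qa2+ cells.

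Between the stages, 11 of 17 mature single-positive genes rose and 15 of 20 immature single-positive genes fell in Qa2+ cells. Averaged over genotypes, S1pr1 rose by 2.33 ± 0.24 (limma log2 difference ± SE, 2 pairs, Benjamini-Hochberg adjusted p = 0.0018), with 1.705 in WT and 2.949 in miR-142-/-. Rflnb, a filamin-binding protein gene, rose by 2.23 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 0.00031), Rag1, a recombinase gene, by 2.31 ± 0.17 (adjusted p = 0.00047) and Foxp3 by 1.91 ± 0.13 (adjusted p = 0.00046). Ifit3, an interferon response gene, was 3.19-fold higher in WT and 3.17-fold in miR-142-/-, the sialyltransferase gene St8sia6 3.09-fold and 2.96-fold, and the cytokine gene Clcf1 3.30-fold and 2.65-fold. Ttc39b and Ly6d rose by 1.70 and 1.49, and Man1c1 was 2.77-fold and 2.89-fold higher.

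Ranked by the smaller of the differences in WT and miR-142-/-, the largest shared decrease in Qa2+ cells was in Akr1c18, 9.44-fold lower in WT and 7.89-fold lower in miR-142-/- (limma, Benjamini-Hochberg adjusted p = 3.3e-05). Ccr4, a chemokine receptor of newly selected thymocytes, was 4.71-fold and 6.91-fold lower, the dynein gene Dnah12 at least 2.67-fold (below background in WT Qa2+ cells) and 4.69-fold, the growth factor gene Fgf2 3.57-fold and 4.45-fold, and the peptide transporter gene Slc15a1 4.30-fold and 3.10-fold. Klra3, Asb2, Chl1, Tmem53 and the chemokine gene Xcl1 also fell, by 2.23, 2.10, 2.27, 1.77 and 2.08.

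With limma and Benjamini-Hochberg adjustment, 600 of 12591 genes were higher and 1051 lower in Qa2+ cells, of which 67 and 84 differed by at least 2-fold. The split was 36.3% higher as deposited, 47.7% after centring and 56.1% after quantile normalization, so the balance of directions is not fixed by these data. The stage differences of the genotypes correlated at 0.66 across genes and at 0.47 across receptor genes. Without a background filter 6.3% of receptor genes passed the limma test, against 12.6% of other genes. Some calls, and some genes counted below as rising or falling, may therefore not reflect expression, and the simulation did not cover such calls. In the fit without the genotype block no gene passed limma's adjusted threshold, with 1544 genes at an unadjusted p under 0.05.

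Of 20 immature single-positive genes, 15 fell and 2 rose in Qa2+ cells (17 and 2 adjusted over the list alone). The heat stable antigen gene Cd24a fell by 1.40, Itm2a by 1.27 and the nuclear receptor gene Nr4a1 by 1.19, while the recombination genes Rag1 and Dntt rose by 2.31 and 1.30. Of 17 mature single-positive genes, 11 rose and 1, Ifngr2, fell (12 and 1 adjusted over the list alone). Klf2, a transcription factor that drives S1pr1, rose by 1.14, and Ms4a6b and Ms4a4c rose by 1.33 and 1.30. Of 21 egress and homing genes, 8 rose and 7 fell (9 and 7 adjusted over the list alone), with S1pr4 and Cxcr4 rising by 1.41 and 1.09 and Plxnd1 falling by 0.90.

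Of 35 interferon response genes, 11 rose and 0 fell (22 and 1 adjusted over the list alone), with Ifit2 and Oas1a rising by 0.78 and 0.69. The list medians were 0.37 in WT and 0.24 in miR-142-/-, above all random lists. Of 24 immediate-early genes, 8 fell and 1, Jun, rose (11 and 4 adjusted over the list alone), with Nr4a2 and Dusp5 falling by 1.69 and 1.36. Of 27 cytokine receptor genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone), including Il18r1, which rose by 1.42, and Socs3, a feedback inhibitor, which rose by 1.32. Of 36 G2 and mitosis genes, 9 rose and 1 fell (14 and 1 adjusted over the list alone), with Ccnb2 and Mki67 rising by 0.76 and 0.69, and of 33 replication genes 5 rose and 2 fell (10 and 3 adjusted over the list alone). Of 30 T cell transcription factors, 4 rose and 7 fell (4 and 8 adjusted over the list alone), with Klf3 rising by 1.10 and Gata3 and Zbtb7b falling by 0.87 and 0.71.

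Among markers of other cells, 6 of 17 double-positive genes rose and 4 fell (6 and 6 adjusted over the list alone): Smad7 and Arpp21 rose by 1.36 and 1.29 with Rag1 and Dntt, while Cd24a fell. The list median was -0.07 in each genotype. Rag1, Rag2, Dntt, Ptcra, Arpp21 and Aqp11 all read higher in Qa2+ than in Qa2- cells in both genotypes, with Rag2 below background throughout. Whether the Qa2+ sort held more double-positive cells was not tested. Of 16 regulatory T cell genes 6 rose and 3 fell (8 and 5 adjusted over the list alone), with Lrrc32 rising by 0.89 and Tnfrsf9 falling by 1.26. Of 15 innate-like genes 2 rose and 5 fell (3 and 7 adjusted over the list alone), and of 17 myeloid and dendritic genes 5 rose and 1, Cd74, fell (7 and 1 adjusted over the list alone). Lyz2, a macrophage lysozyme gene, rose by 1.15 but was near the background threshold in both groups of Qa2- cells. The remaining lists had at most 3 genes passing in either direction, among them Gadd45b, which fell by 1.32, and Bcl2l1, an anti-apoptotic gene, which fell by 1.01.

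**Figure D4:**
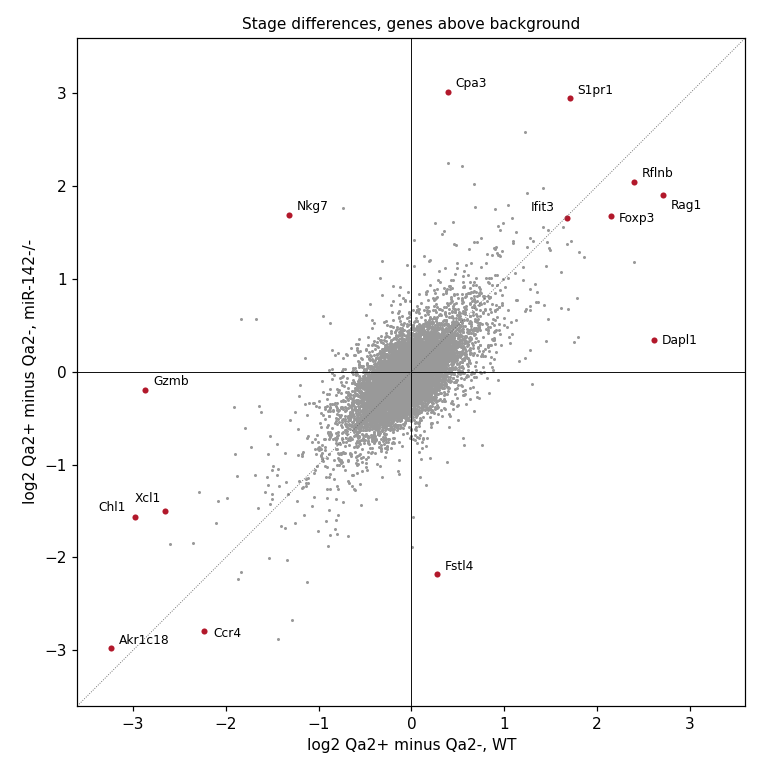
Log2 difference between Qa2+ and Qa2- cells in WT (horizontal) and miR-142-/- (vertical) for 12591 genes above background, 1 point per gene, with named genes in red and a dotted line of equality. Rag1, Rflnb and S1pr1 lie high in both, Akr1c18 and Ccr4 low in both, and Nkg7, Cpa3, Gzmb and Dapl1 away from the line.

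In WT, 66 genes were at least 2-fold higher and 92 lower in Qa2+ cells, a split of 41.8% higher that became 54.3% after quantile normalization. Rag1 was 6.57-fold higher, Dapl1, a gene of mature naive T cells, 6.12-fold and the innate receptor gene Tlr1 5.27-fold higher. Chl1, an adhesion molecule gene, was 7.88-fold lower, Gzmb 7.29-fold, Xcl1 6.31-fold and Klra3, below background in WT Qa2+ cells, at least 4.46-fold lower.

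In miR-142-/- cells, 90 genes were at least 2-fold higher and 103 lower in Qa2+ cells, a split of 46.6% higher that became 51.1% after centring and 52.3% after quantile normalization. S1pr1 was 7.72-fold and the adhesion gene Mpzl2 4.76-fold higher. The mast cell protease gene Cpa3 and the lipid flippase gene Atp8b4, both below background in Qa2- cells, were at least 6.66-fold and 5.34-fold higher. The activin receptor gene Acvr1c was 7.36-fold lower, Ccr4 6.91-fold and Ly96, a co-receptor gene for lipopolysaccharide, 4.80-fold lower, and Exph5, below background in Qa2+ cells, at least 4.59-fold lower.

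The difference of differences, the stage difference in miR-142-/- minus that in WT, was at least 2-fold toward higher values for 42 genes and toward lower values for 31. Genes with the most positive difference of differences were Nkg7 (3.01), Gzmb (2.67), Cpa3 (2.63), the chemokine gene Ccl3 (2.51) and Klrd1 (2.41). Those with the most negative were Fstl4 (-2.46), Dapl1 (-2.27), Lix1 (-1.90), the interleukin-10 receptor gene Il10ra (-1.58) and the integrin gene Itgb8 (-1.54). Gzmb and Klrd1 were below background on both miR-142-/- arrays, Cpa3 and Ccl3 were above it only in miR-142-/- Qa2+ cells and Lix1 only in miR-142-/- Qa2- cells, so the values and ranks of these genes rest partly on readings at the floor. Fstl4 read 8.17 only in miR-142-/- Qa2- cells and at most 5.99 elsewhere. The G2 and mitosis list had a median difference of differences of -0.45, below all random lists, since its stage median was 0.57 in WT and 0.07 in miR-142-/-. The immediate-early list had a median of -0.24, also below all random lists, and the innate-like list had 0.34, above all of them.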

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

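Except for the test of array scale, every test of an explanation below was chosen or run after some of the values it uses had been seen. Those of genes that escape X inactivation and of the wider region around Mir142 were first drawn up as blind tests, but Kdm6a and several genes near Mir142 had already been seen, so they count as chosen afterwards.

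Of 524 genes named or listed here, 4 were at least 1.5-fold apart in opposite directions between groups, which was not tested, since each group has 1 array. Among all genes above background, 2 did so for genotype and 4 for stage, which adds Cybrd1 and Sfrp2, named after their values were seen. Nkg7 was lower in Qa2+ than Qa2- cells in WT (-1.32) and higher in miR-142-/- (1.69), a difference of 3.01. Ccl3 met the rule with a difference of 2.51, but both WT readings (5.77 and 5.03) were below background, so only its higher value in miR-142-/- Qa2+ cells (7.49) was measured and no opposite direction is shown. Itgb8 went the other way, with 0.76, -0.79 and a difference of -1.54. Dapl1 was higher in miR-142-/- in Qa2- cells (1.53) and lower in Qa2+ cells (-0.74), a difference of -2.27. Among probe sets with no listed gene, which enter no comparison, 17 were at least 2-fold higher and 12 at least 2-fold lower in miR-142-/- in both populations.

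The first pattern is that Xist was high and Y-linked genes were below background in both WT arrays, with the reverse in both miR-142-/- arrays. Pools of both sexes as labelled would put Y-linked genes 0.91 apart, whereas the smallest of 6 differences was 4.66, which argues against them. That value, of Kdm5d in Qa2- cells, uses a WT reading below background. Measured against the threshold, Kdm5d was still at least 14.4-fold higher in miR-142-/-. Arrays of cells from females in WT and males in miR-142-/- are a candidate explanation. Of 8 differences of the X escape genes Kdm5c, Ddx3x, Eif2s3x and Kdm6a, 7 were below 0, and Ddx3x in Qa2+ cells was at 0.10, so that test left it open. Genotype and sex cannot be told apart on these arrays, and no biological explanation was tested.

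The second pattern is the higher Rnf43 and Tspoap1 in miR-142-/- in both populations. Both lie within 5 genes of Mir142. Of the 10 nearest genes above background, 2 differed by 1.5-fold in both populations, against 4.9% of other genes (one-sided Fisher's exact p = 0.083). These 2 are Rnf43 and Tspoap1 themselves, so the count restates the pattern and decides nothing. Of the next 100 genes 7 did (7.0%, 95% exact interval 2.9% to 13.9%, one-sided Fisher's exact p = 0.22). An effect of the altered locus on its neighbours and a differing chromosome segment may each contribute and cannot be told apart here, because few genes are involved. Regulation of these genes by miR-142 itself was not tested.

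The last pattern is the lower proliferation genes in miR-142-/- cells. Offsets that remain between the deposited arrays are too small to give it. The genotype medians of all genes above background lay between -0.032 and 0.044 after centring or quantile normalization. The highest of 8 list medians was then -0.92, still below all random lists. RMA had already equalised the arrays, so this could hardly come out otherwise, and a shift that RMA hides was not tested. Cycling double-positive thymocytes in the WT sort stay open: the medians of Rag1, Rag2, Dntt, Ptcra, Arpp21 and Aqp11 were 0.33 and 0.18, past the bound set against them, but Rag2 was below background, members went both ways (Rag1 -0.61 in Qa2+ cells) and Cd8b1 was lower. Fewer innate-like or effector cells in the miR-142-/- sort may contribute. The highest of 4 list medians was -0.59, no gene is shared with the proliferation lists, and Lgals1, Crip1 and Il2rb, read at over 10 in WT, were lower. The lists did not all run in parallel, however. By stage in WT the innate-like median was -0.60 and that of G2 and mitosis genes 0.57. Effector and DNA replication genes had stage medians of 0.10 and 0.12 there. The regulatory T cell list, with genotype medians of -0.03 in Qa2- and -0.51 in Qa2+ cells, was not part of that test. Sex stays open, with 0 pairs of arrays of the same apparent sex, as does an effect of miR-142 on division itself.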

How the results depend on the processing

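Centring, quantile normalization, other background filters and the mean of all probe sets kept the total of each count of differing genes within 1.5 times its value. By direction, the averaged stage counts went further, to 977 higher with quantile normalization and 1593 lower with no filter on dim probe sets. After seeing the data, X and Y genes were left out of the genotype counts and the difference of differences. The genes of both proliferation lists, but not other cell cycle genes, were left out of the genotype counts. These totals also stayed within 1.5 times. Thresholds moved counts by construction. At 1.5-fold they were 862 for genotype in Qa2- cells, 1189 for genotype in Qa2+ cells, 804 for stage in WT, 792 for stage in miR-142-/- and 430 for the difference of differences. Genotype differences shared by both populations numbered 213 at 2-fold and 1770 with limma. Its p-values rest mostly on a prior drawn from all genes, and otherwise on the spread between sorted populations of 1 pool per genotype. For the averaged stage difference, requiring 2-fold left 151 genes, and the fit with no replicate block (no genotype block) called 0 genes with limma, against 1544 at an unadjusted p under 0.05. Of 112 list medians, 51 lay outside the central 95% of random lists, and 49 to 55 did under the alternatives. For independent lists of unrelated genes 5.6 would be expected. These lists hold related genes and share some, and the comparisons share arrays, so the excess does not measure results beyond chance. With the mean of the list, miR-142 targets had 0.09 in Qa2- and 0.07 in Qa2+ cells and were no longer outside that range. The cytokine receptor value in Qa2- cells turned to -0.01, and the cause was not tested. Of all list values under the alternatives, 559 moved by less than the spread of random lists, 112 moved further or crossed that range and 1 changed sign. The other lead lists below moved by more than the spread of random lists but kept their direction and side. Quantile normalization gave -0.76 for immature and 0.77 for mature genes, 0.44 for interferon genes and 0.66 for mitosis genes by stage in WT, 0.29 and 0.13 for the last 2 in miR-142-/-, and 0.31 for miR-142 targets in Qa2- cells. Centring gave -0.29 and -1.16 for interferon and mitosis genes by genotype in Qa2- cells and 0.43 for interferon genes by stage in WT. List means gave -0.66 for immature genes by stage in WT, -0.52 for mature and -1.28 for mitosis genes in Qa2- cells, and -0.51 and -1.05 for interferon and replication genes in Qa2+ cells. All members gave -1.15 for mitosis genes in Qa2- cells and the mean of probe sets -1.64 in Qa2+ cells. Of 435 alternative values of named genes, 433 moved by less than the spread of receptor genes. The 4 alternatives on miR-142 seed sites were not run. Leaving out a pool leaves 1 pair and no test, and differences of dim genes are compressed toward 0.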

Other observations

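The gene groups here were chosen after their values were seen. Of 7 Hoxa genes above background, homeobox regulators of body patterning, 6 were at least 1.5-fold higher in miR-142-/- in both populations. The medians were 1.65 in Qa2- and 1.39 in Qa2+ cells. They lay above all random lists, but with a group chosen after its values were seen, that rank tests nothing. Hoxa5, Hoxa6 and Hoxa7 were higher by 2.26, 1.94 and 1.70 in Qa2- cells. In WT, Hoxa2 in both populations and Hoxa3 and Hoxa9 in Qa2- cells read below background, so their differences are less certain. The 3 Hoxb genes above background had medians of -0.05 and 0.09.

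Replication-dependent histone genes had medians of -0.18 and -0.55 in Qa2- and Qa2+ cells, and the members went both ways. Of 23 genes, 6 and 11 were at least 1.5-fold lower and 4 and 4 higher. H2bc3 and H2ac4 differed by -1.62 and -1.69 in Qa2- cells, whereas H2bc4 differed by 1.89 and H1f2 by 0.99. Close sequence similarity among histone genes makes single values uncertain. The 54 ribosomal protein genes above background had medians of -0.19 and -0.12, with 1 gene at least 1.5-fold lower in each population.

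Cpa3, a mast cell protease gene, read 8.60 in miR-142-/- Qa2+ cells and at most 5.58 on the other arrays, while the mast cell protease gene Mcpt4 was below background.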
